A study of Paracoccus denitrificans with 6 samples.

How the data were processed

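Total RNA of 3 control and 3 florfenicol-exposed samples of Paracoccus denitrificans ATCC19367 was sequenced; per the labels' protocols, cells were pelleted, RNA was extracted with Trizol and libraries followed Illumina protocols. The submitters' processing notes name bcl2fastq 2.17.1.14 and Bowtie2 2.2.6 with no role. The read counter, its strand setting, the genome build and the annotation are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited table lists 5197 genes with a locus identifier, a symbol for 664 of them, a gene size, and a read count and an FPKM value per library.

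The deposited read counts are whole numbers, not normalized, per the file headers and values. The deposited FPKM values are counts scaled for gene size and for the library total: recomputing them from the counts, the sizes and each library's total gave differences of at most 0.005. Of the sizes, 98.1% are multiples of 3, so most are coding lengths without untranslated regions; RNA genes such as ssrA can have such a size by chance. No column of the table was left out of use as belonging to another sample. No reference genome was used here, so no coordinates or product names are given and genes were placed in lists by symbol alone. The order of locus numbers served as the order of neighbouring genes.

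Samples were grouped by the treatment in their labels. Library totals ran from 10594275 to 14368954 counts. Total counts, principal components and Spearman correlations were compared first; within groups the lowest chi-square per degree of freedom between libraries was 28.96, so no pair differed by sampling noise alone. The design had foreseen limma on FPKM, with edgeR in its place if the file held counts. It did, so the main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) on the counts with TMM factors, with no covariate, and Benjamini-Hochberg adjustment. Standard errors of log2 fold changes were the absolute log2 fold change over the square root of the F statistic. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, which left 4684 and removed 513. An adjusted p under 0.05 was called. FPKM means and SDs in the text are on the deposited scale, and fold changes come from the edgeR fit. The biological coefficient of variation was 20.8%.

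Before the data were examined, 23 gene lists were fixed by symbol pattern: nitrate reduction and transport, nitrite, nitric oxide and nitrous oxide reduction, ribosomal proteins, translation factors, ribosome assembly, aminoacyl-tRNA synthetases, RNA polymerase, drug efflux and phenicol resistance, heat shock, oxidative stress, DNA damage, complex I, the bc1 complex and terminal oxidases, ATP synthase, the tricarboxylic acid cycle, cytochrome c maturation and heme, molybdenum cofactor, iron uptake, flagellum, one-carbon oxidation, polyhydroxyalkanoates, nitrogen assimilation, and protein secretion. The 17 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over lists. Shares of summed FPKM were compared with exact permutation tests, over all rows, since the table does not mark which rows encode proteins.

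The genes named in the text followed a rule fixed before the data were examined. It took the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean FPKM of at least 10 in the higher group and groups that do not overlap. It added fixed genes of denitrification, translation and stress. No row carried the symbols narG, nirS, norB, norC, floR, rplD, rplV, tufA, groEL or katA, so these could not be looked up. The rule also took up to 3 called members of each list with the largest change and the one that moved most against the rest. Where none was called it took the member of highest FPKM, and it took the gene of highest FPKM in each group. The other list members named, the genes in the map of neighbouring loci and those in the closing section were chosen after their values were seen. Genes without a symbol are given by identifier for at most 2 that rose and 2 that fell. There were 20 sets of rows with the same symbol and size, 43 rows in all, of which 53.5% fell under the filter against 3.54% of rows with a symbol of their own. Such copies may share reads, which was not tested, so their values are uncertain; both groL, both uvrB and both macB rows were not tested.

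The test was tried on simulated counts for the 4684 genes, 200 of them changed. It recovered 2.99% of genes changed 1.5-fold, 61.2% of those changed 2-fold and 98.5% of those changed 4-fold, with 6 false calls among 114. The real comparison called 1383 genes, which makes the adjusted threshold less strict, so these shares do not carry over to it. A simulated list of 12 genes shifted by 0.5 on the log2 scale was found by camera, and 7 of 100 unshifted lists fell under 0.05 without adjustment. The simulated genes were drawn independently. In the real lists the estimated correlation ran from -0.0595 (DNA damage) to 0.662 (ribosomal proteins). The simulation therefore cannot give the error rate of camera on correlated lists.

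Alternatives fixed before the data were examined were limma on log2(FPKM + pseudocount) with pseudocounts of 1, 0.1 and 5, with median-ratio, quantile or equal-sum scaling and without trend, no filter or a filter at a mean FPKM of 10, a fold of at least 2, the replicate number as a block, each library left out in turn, camera with an estimated correlation, fry, and shares without the 10 genes of highest FPKM. Alternatives chosen after seeing the data were DESeq2 1.42.0, edgeR with median-ratio factors or with library totals only, removal of a gene-length trend per library, leaving out rows of 200 bases or less, and the denitrification share without nosZ. Figures were drawn with matplotlib 3.10.9.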

Results

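Total RNA of Paracoccus denitrificans ATCC19367, a soil bacterium that respires oxygen or, without it, nitrate and its reduction products down to nitrogen gas, was sequenced from 3 control and 3 florfenicol-exposed samples. Florfenicol is a phenicol antibiotic that binds the large ribosomal subunit and stops peptide bond formation. The dose, the length of exposure and the growth conditions are not given in the sources used here. The total counts per library were 14132201, 14368954 and 12771608 in control replicates 1, 2 and 3, and 12546995, 10594275 and 12728934 in florfenicol replicates 1, 2 and 3. The file listed 5197 genes, of which 664 carried a symbol, and between 4938 and 4979 had reads in each library. Because no product names or coordinates were used here, the groups described rest on the genes with a symbol. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

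The libraries separated by treatment. The first principal component of the log2 normalised counts held 65.2% of the variance and placed the controls at -35.76, -23.8 and -8.346 and the florfenicol libraries at 13.08, 22.47 and 32.35, in the order of their replicate numbers. Spearman correlations across genes ran from 0.9778 to 0.993 within groups and from 0.9398 to 0.9794 between them. Control replicate 3 correlated with florfenicol replicate 2 at 0.9794 and with control replicate 1 at 0.9778. The gene with the most reads in the controls, the unnamed EO213_07530, took 7.02% ± 0.826 (SD, n = 3) of all reads in the controls and 3.94% ± 0.137 in the florfenicol libraries.

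**Figure D1:**
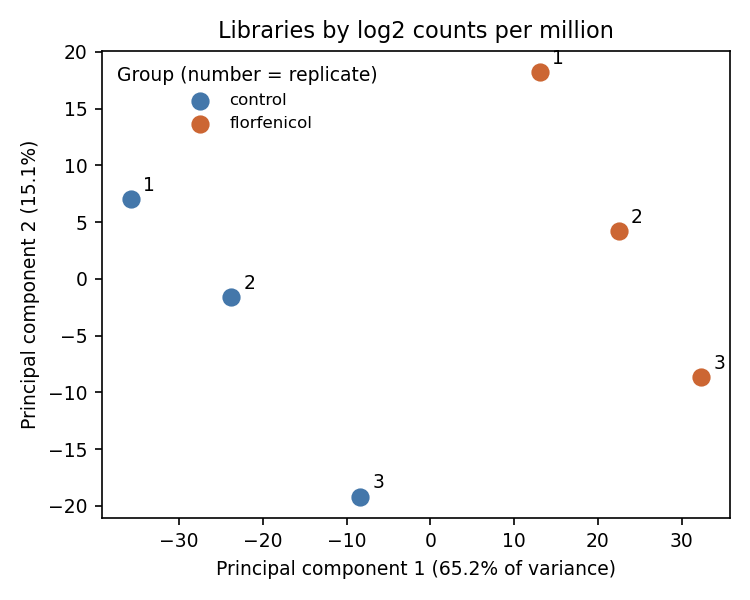
Principal components of log2 normalised counts over the tested genes, 1 point per library, numbered by replicate (blue, control; orange, florfenicol; n = 3 per group). The horizontal axis holds 65.2% of the variance and separates the groups. On this axis alone, control replicate 3 at -8.346 and florfenicol replicate 1 at 13.08 are the nearest libraries of opposite groups.

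The comparison of exposed with unexposed cells asks which transcripts change under florfenicol. The largest rise among named genes was that of catB, from 47.0 ± 19.2 FPKM (SD, n = 3) in the controls to 5156 ± 177 with florfenicol, a log2 fold change of 6.75 (SE 0.298, adjusted p = 3.18e-05, edgeR quasi-likelihood test). The symbol catB is used both for chloramphenicol acetyltransferases and for an enzyme of catechol breakdown, and the file pairs it with no product. Its size in the file is 636 bases, which was not compared with known genes of either kind. The unnamed EO213_21590 rose from 39.1 ± 5.90 to 1223 ± 87.3 FPKM, a log2 fold change of 4.92 (SE 0.196, adjusted p = 2.86e-05). ssrA, the transfer-messenger RNA that frees stalled ribosomes, rose from 1268 ± 369 to 4823 ± 375 FPKM, or 3.72-fold (adjusted p = 0.00167). nosZ, the nitrous oxide reductase, fell from 9478 ± 1106 to 3148 ± 231 FPKM, a log2 fold change of -1.65 (SE 0.149, adjusted p = 0.000974).

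In all, 722 of 4684 tested genes were higher and 661 were lower with florfenicol at an adjusted p under 0.05, which is 29.5% of those tested. A fold of at least 2 was reached by 177 of the higher and 308 of the lower genes. Among the 619 tested genes with a symbol, 126 were higher and 99 lower. The groups did not overlap for 45.6% of the tested genes, where chance gives 10%. The counts depended on which library was left out: without control replicate 2 the test called 133 higher and 230 lower, and without florfenicol replicate 2 it called 194 and 231. Without control replicate 1 it called 350 and 389, and without florfenicol replicate 3 it called 367 and 389. Fewer samples alone lower such counts. Both replicates 2 lay between the others of their group on the first principal component (-23.8 and 22.47), so leaving them out kept the farthest pair. No call was reversed in these fits. With each library rescaled to the same sum of FPKM and tested with limma, 36.6% of the calls were higher against 52.2% in the edgeR test, with 471 higher and 815 lower, and the median of all genes lay at -0.11 on the log2 scale.

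Next to catB and ssrA, 6 more named genes made up the largest rises among those with a mean FPKM of at least 10 in the higher group and non-overlapping groups. lpdA (EO213_22990), a dihydrolipoyl dehydrogenase, rose 3.53-fold (log2 fold change 1.82, SE 0.391), with a wide spread in the florfenicol libraries at 144 ± 89.8 FPKM and a log2 fold change of 1.22 without florfenicol replicate 1. metB, of methionine synthesis, rose 3.02-fold to 32.7 ± 8.41 FPKM. prmC, which methylates peptide release factors, rose 2.83-fold to 250 ± 33.1 FPKM. nusB, a transcription antitermination factor of the ribosomal RNA operons, rose 2.64-fold, cobD of cobalamin synthesis 2.64-fold, and queC of queuosine synthesis 2.56-fold. Adjusted p-values of these 6 lay between 0.00277 and 0.0353. Leaving out control replicate 2 ended the calls of lpdA (EO213_22990), prmC and queC, with adjusted p = 0.062, 0.0513 and 0.121. The call of queC also ended without control replicate 1, florfenicol replicate 2 or florfenicol replicate 3, and in the limma fit on libraries rescaled to the same sum (adjusted p = 0.054). EO213_18540, the gene with the highest FPKM in the florfenicol libraries, rose from 37303 ± 4758 to 63470 ± 573.

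The largest falls among named genes included 3 genes of phosphate uptake and its control. pstC and pstA, which form the membrane channel of the phosphate transporter, fell with log2 fold changes of -2.49 (SE 0.175, adjusted p = 0.000352) and -1.91 (SE 0.177, adjusted p = 0.000989). phoU, a negative regulator of the phosphate response, fell with -1.63 (SE 0.155, adjusted p = 0.00111). adhP, an alcohol dehydrogenase, fell from 165 ± 92.9 to 22.5 ± 8.09 FPKM (log2 fold change -2.96, and -2.35 without control replicate 1), and bioB (EO213_00845), a biotin synthase, from 520 ± 127 to 113 ± 45.2 FPKM. The unnamed EO213_24095 fell from 43.2 ± 12.4 to 4.89 ± 2.25 FPKM (log2 fold change -3.21, and -2.28 in limma with a pseudocount of 5). aceB, a malate synthase of the glyoxylate bypass, had the most negative log2 fold change, -5.38 (SE 1.27, adjusted p = 0.0193), but its controls held 190.74, 53.39 and 3.76 FPKM against 3.68, 1.28 and 1.40 with florfenicol. Its log2 fold change was -3.79 without control replicate 1, -6.04 without florfenicol replicate 1, and between -4.10 and -2.72 in limma fits. The call of aceB ended without control replicate 2, florfenicol replicate 2 or florfenicol replicate 3, with adjusted p up to 0.0728. It also ended in the limma fits on FPKM (adjusted p = 0.0517 with a pseudocount of 1), except that with a pseudocount of 0.1.

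**Figure D2:**
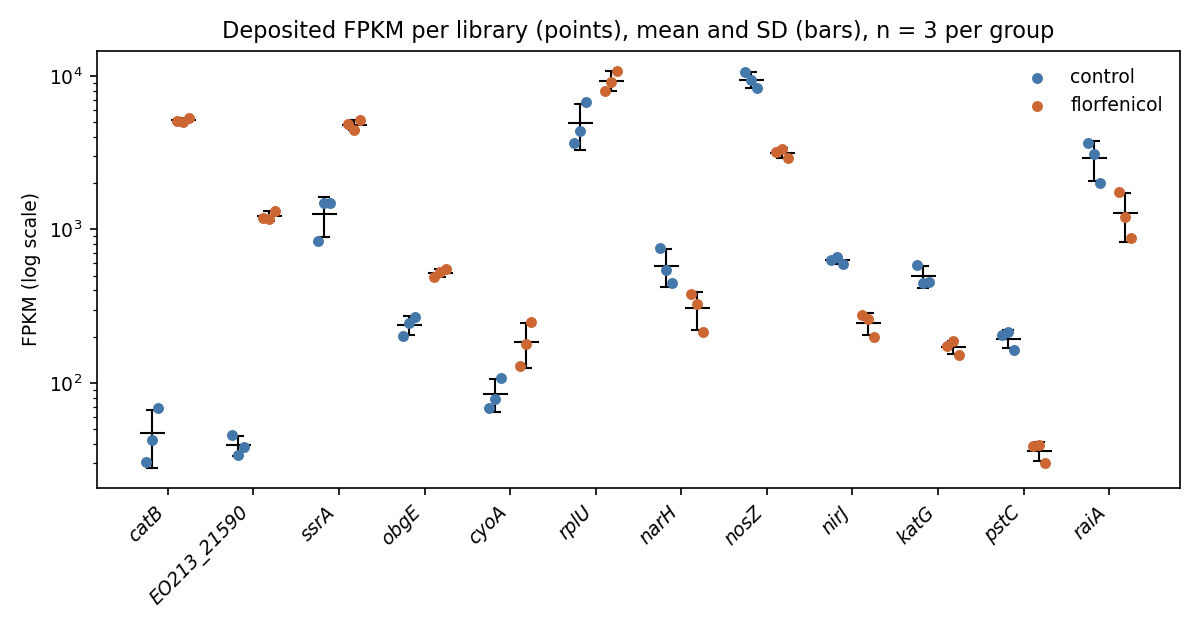
Deposited FPKM of 12 genes on a log axis, 1 point per library (blue, control; orange, florfenicol), with the mean and SD as bars (n = 3 per group). catB goes from 47.0 to 5156 and nosZ from 9478 to 3148, and the groups of these 12 genes do not overlap.

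For denitrification, all 3 tested genes of nitrite, nitric oxide and nitrous oxide reduction fell, with a median log2 fold change of -1.42, and the same 3 passed when adjusted over the list alone. These were nosZ, nosD, a maturation factor of nitrous oxide reductase (697 ± 26.7 to 355 ± 57.5 FPKM), and nirJ, of heme d1 synthesis (630 ± 35.6 to 245 ± 41.0 FPKM). Of 6 tested genes of nitrate reduction and transport, 3 fell and none rose. The 3 that fell belong to the membrane-bound nitrate reductase: narH went from 582 ± 159 to 306 ± 83.8 FPKM, narJ had a log2 fold change of -0.91 (SE 0.214) and narI of -0.89 (SE 0.192). The other 3, napA, napE and napH, carry symbols used for the periplasmic reductase and lay above 0, with napA at 0.25 (SE 0.201, adjusted p = 0.375). Of these, napH lay near the filter, at 1.19 ± 0.977 FPKM in the controls and 1.77 ± 0.110 with florfenicol. Whether napH belongs to that reductase was not tested. Adjusted over the list alone, 3 nitrate genes fell and 1 rose. The list as a whole did not differ from other genes (camera, adjusted p = 0.562). Each nar call ended without control replicate 2 (adjusted p = 0.0644 for narJ and 0.0626 for narI) or without florfenicol replicate 2 (0.08 for narH). The calls of narH and narJ also ended without control replicate 1, and that of narH without florfenicol replicate 3. Both lists together, 11 genes, held 1.10% ± 0.174 (SD, n = 3) of the summed FPKM in the controls and 0.371% ± 0.0451 with florfenicol. nosZ made up 79.3% of this difference, and the other 10 genes held 0.281% ± 0.0420 and 0.130% ± 0.0271. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. No row carried the symbols narG, nirS, norB or norC. Such genes, if listed without a symbol, are not in these lists or in the share.

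**Figure D3:**
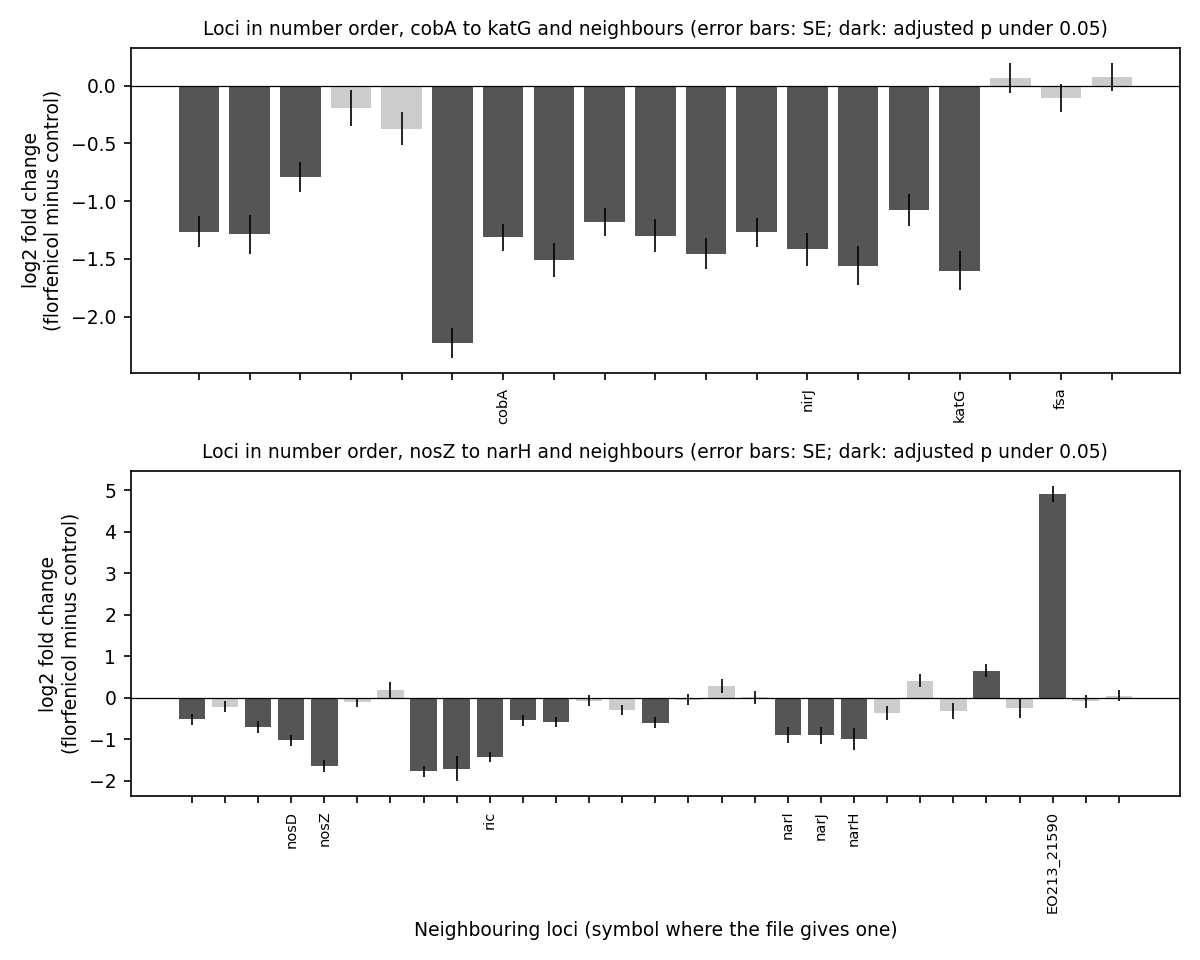
Log2 fold change (florfenicol minus control) of neighbouring loci in the order of their locus numbers, with the SE as error bars; dark bars have an adjusted p under 0.05, and symbols are shown where the file gives one. The upper panel runs through cobA, nirJ and katG, which lie in a stretch of 11 lower loci with a median of -1.42; the lower panel runs from nosD and nosZ past narI, narJ and narH to EO213_21590 at 4.92.

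Among genes of the translation machinery, 4 of 6 ribosomal proteins with a symbol rose and none fell, also when adjusted over the list alone, with a median log2 fold change of 0.58; rpmG rose 2.24-fold, rplU 1.86-fold and rplK 1.53-fold. Of 13 genes of ribosome assembly and ribosomal RNA modification, 4 rose and none fell, and 9 rose when adjusted over the list alone. obgE, a GTPase of large-subunit assembly, rose from 239 ± 34.1 to 523 ± 31.9 FPKM (adjusted p = 0.00272), and the methyltransferase genes rlmN and rlmB rose 1.71-fold and 1.67-fold. Against other genes, both lists had an adjusted p = 0.0569 by camera and did not pass. With an estimated correlation, the adjusted p was 0.701 for both. The calls of rpmG, rplU, rplK and rlmN ended when any 1 of control replicates 1 and 2 and florfenicol replicates 2 and 3 was left out (adjusted p up to 0.139, 0.0837, 0.105 and 0.118), and that of rlmB without control replicates 1 or 2 or florfenicol replicate 2 (up to 0.0774). In limma fits, calls ended for rplU with quantile normalization (adjusted p = 0.0958), for rpmG on libraries rescaled to the same sum (0.0537) and without trend (0.0511), and for rlmN in 4 fits (0.0542 without trend, up to 0.0725 on rescaled libraries). The 6 ribosomal protein genes held 1.92% ± 0.448 of the summed FPKM in the controls and 2.77% ± 0.275 with florfenicol (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible). The largest member was rpsU, at 10947 ± 4025 FPKM in the controls and 16297 ± 1173 with florfenicol. It was not called in the edgeR test (adjusted p = 0.13), so the share leans on a gene that did not pass.

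Of 11 translation factors, 4 rose and 1 fell, and 4 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.303). def, which removes the formyl group from new peptides, rose 2.07-fold and smpB, the protein partner of ssrA, 1.96-fold. raiA, a factor that binds idle ribosomes, fell from 2923 ± 845 to 1277 ± 444 FPKM (log2 fold change -1.27, SE 0.301, adjusted p = 0.0195). The calls of def and smpB ended without control replicate 2 (adjusted p = 0.0606 and 0.0529), that of smpB also without florfenicol replicate 2, and that of raiA without 4 of the 6 libraries in turn, control replicates 1 and 2 and florfenicol replicates 2 and 3 (up to 0.0741). The elongation factor gene tuf had 2 rows of 1176 bases each, at log2 fold changes of 0.25 (EO213_11610) and -0.27 (EO213_11725). Neither passed the test, and because rows of the same symbol and size may share reads, which was not tested, their values are uncertain. Of 6 genes on the list of aminoacyl-tRNA synthetases, thrS rose 1.51-fold (adjusted p = 0.0436) and none fell; 3 rose and 2 fell when adjusted over the list alone. The median was 0.37 and the mean -0.05, since 2 members share the symbol cysT, which names a sulfate transport gene, and lay at -1.05 and -1.13 (camera upward, adjusted p = 0.646). The call of thrS ended without 4 of the 6 libraries, control replicates 1 and 2 and florfenicol replicates 2 and 3 (adjusted p up to 0.129), in 4 limma fits (up to 0.0797) and in the edgeR test without the filter (0.0502). Of 11 genes of RNA polymerase and its elongation factors, nusB and mfd rose, the latter 1.46-fold, and rpoH, the heat shock sigma factor, fell 1.55-fold; adjusted over the list alone, 3 rose and 1 fell (camera, adjusted p = 0.303). Calls ended for mfd without those 4 libraries (adjusted p up to 0.112) and in limma fits with quantile or equal-sum scaling (0.0584 and 0.0694), and for rpoH without control replicate 2 or florfenicol replicate 2 (up to 0.0724).

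Among respiratory genes, 6 of 13 genes of the cytochrome bc1 complex and terminal oxidases rose and none fell, and 7 rose when adjusted over the list alone. All 4 cyo genes, which encode a quinol oxidase, were among them: cyoD rose 2.37-fold (17.3 ± 3.30 to 42.1 ± 0.554 FPKM), cyoA 2.15-fold and cyoC 1.73-fold. The list had an adjusted p = 0.0569 by camera, and an adjusted p = 0.701 with an estimated correlation. Of 5 complex I genes, nuoI fell 1.51-fold and none rose, also when adjusted over the list alone (camera, adjusted p = 0.303). atpD, the only ATP synthase gene tested, lay at a log2 fold change of -0.11 (adjusted p = 0.626). Of 12 genes of the tricarboxylic acid cycle, 3 fell and 1 rose, also over the list alone (camera, adjusted p = 0.303). gltA, the citrate synthase, fell from 1570 ± 26.9 to 921 ± 225 FPKM. All other called members carry the symbol lpdA. lpdA (EO213_11000) fell 1.80-fold and lpdA (EO213_10710) 1.54-fold, while lpdA (EO213_22990) was the one that rose. They were placed on the list by symbol alone, and whether each serves the cycle was not tested. Single libraries ended the calls of cyoA (control replicates 1 and 2 and florfenicol replicate 2, adjusted p up to 0.0799) and, for both control replicate 2 and florfenicol replicate 2, of nuoI, gltA and lpdA (EO213_11000) (up to 0.0965, 0.0859 and 0.065).

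Of 8 genes of cytochrome c maturation and heme synthesis, ccmA and ccmB, subunits of a heme exporter, rose 1.79-fold and 1.73-fold, and 2 fell, with ccmE, the heme chaperone, falling 2.03-fold; 2 rose and 3 fell when adjusted over the list alone (camera, adjusted p = 0.685). Of 7 genes of the molybdenum cofactor and molybdate uptake, 4 rose and none fell, and 5 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 0.139). moaC rose 1.74-fold, moaD 1.63-fold and modC, of molybdate uptake, 1.53-fold. The calls of modC and moaD ended without control replicate 2 or florfenicol replicate 2 (adjusted p up to 0.0802 and 0.0965), and that of moaD also without control replicate 1 or florfenicol replicate 1 and in the limma fit on rescaled libraries (0.0618).

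Of 16 genes of protein secretion and membrane insertion, 6 rose and none fell, also when adjusted over the list alone. secG and secE, small subunits of the protein-conducting channel, rose 2.19-fold and 2.02-fold, and lepB, the signal peptidase, 1.72-fold. The list had an adjusted p = 0.0569 by camera, and an adjusted p = 0.738 with an estimated correlation. The call of secE ended without control replicates 1 or 2 or florfenicol replicates 2 or 3 (adjusted p up to 0.111) and in the limma fit on rescaled libraries (0.0545), and that of lepB without control replicate 2 (0.0524).

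Of 8 genes of oxidative stress defence, 4 fell and 1 rose, and 5 fell and 3 rose when adjusted over the list alone (camera, adjusted p = 0.139). katG, a catalase-peroxidase, fell from 498 ± 80.0 to 171 ± 17.4 FPKM. The methionine sulfoxide reductase genes msrB and msrP fell 2.93-fold and 2.52-fold, and the glutaredoxin gene grxC rose 1.60-fold. Of 10 heat shock chaperones and proteases, clpA and clpB fell 1.63-fold and 1.51-fold and hspQ rose 1.86-fold, also over the list alone (camera, adjusted p = 0.761). Of 9 DNA damage genes, radA rose 1.53-fold and none fell, also over the list alone (camera, adjusted p = 0.303). recA stood at 691 ± 49.3 FPKM in the controls and 715 ± 35.9 with florfenicol, a log2 fold change of 0.00 (SE 0.117) whose sign depended on the scaling. Calls ended for clpA, hspQ and grxC without control replicates 1 or 2 or florfenicol replicates 2 or 3 (adjusted p up to 0.133, 0.145 and 0.102). They ended for clpB and radA without control replicate 2 or florfenicol replicate 2 (up to 0.0671 and 0.0589), and for clpA and hspQ in 6 limma fits each (up to 0.0745 and 0.076). The call of hspQ also ended in edgeR without the filter (0.0511), with a filter at a mean FPKM of 10 (0.0522) and with median-ratio factors (0.0526).

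**Figure D4:**
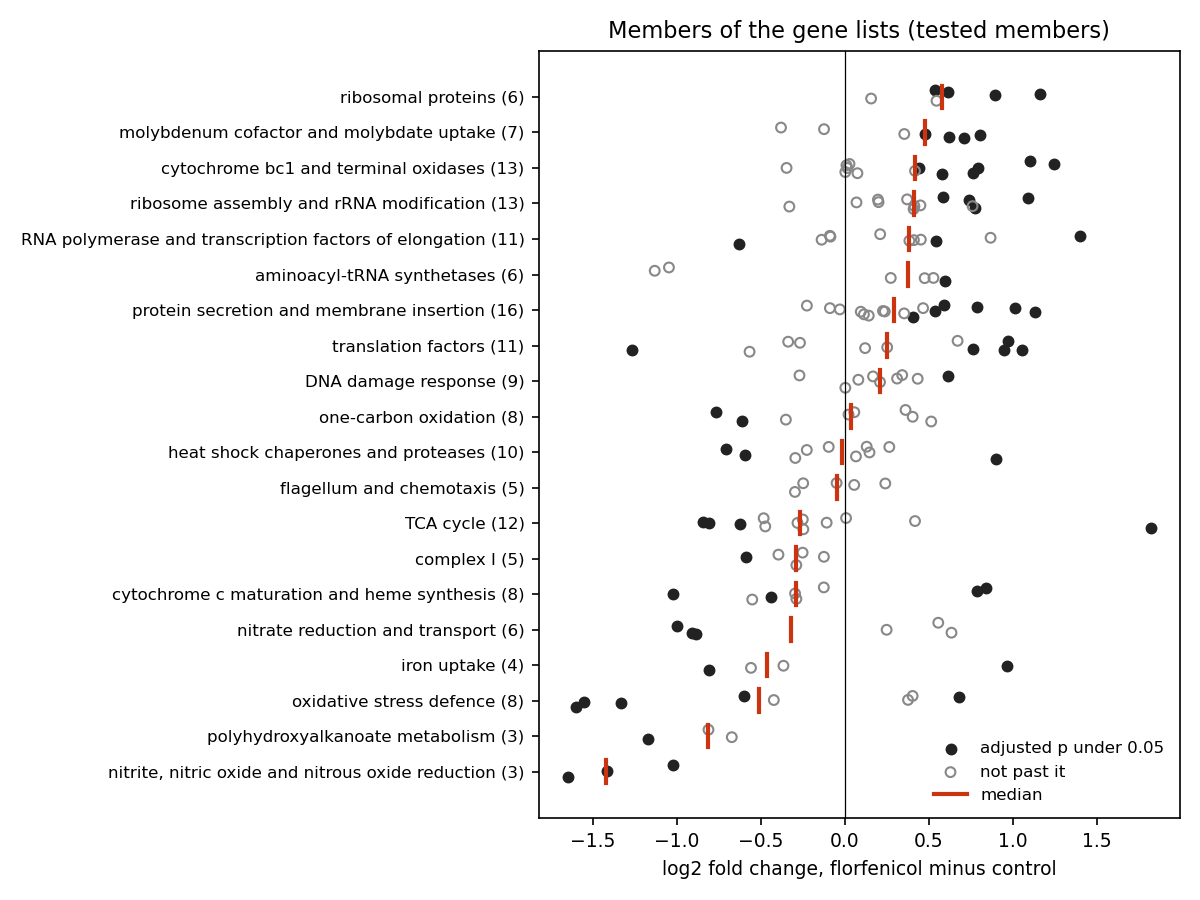
Log2 fold change (florfenicol minus control) of the tested members of each gene list with at least 3 of them, 1 point per gene; filled points have an adjusted p under 0.05, red lines mark medians, and the number of tested members stands in parentheses. Medians run from -1.42 for nitrite, nitric oxide and nitrous oxide reduction to 0.58 for ribosomal proteins.

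Of 3 polyhydroxyalkanoate genes, phaC, the synthase of this carbon store, fell 2.25-fold, and 3 fell when adjusted over the list alone. Of 4 iron uptake genes, fhuB rose 1.96-fold and exbB fell 1.75-fold, also over the list alone. Of 8 genes of one-carbon oxidation, fdhE and fghA fell 1.70-fold and 1.53-fold and none rose, also over the list alone; the median was 0.04 and the mean -0.05 (camera downward, adjusted p = 0.646). Of 5 flagellar genes, none passed the test, also over the list alone, with flgI at 7.98 ± 2.99 and 6.85 ± 0.886 FPKM (camera, adjusted p = 0.9). glnA, the only tested gene of nitrogen assimilation, lay at a log2 fold change of -0.67 (adjusted p = 0.0723). Over this list of 1 gene nothing is adjusted, and its unadjusted p was 0.0254 (edgeR test). Unadjusted, 2031 of 4684 tested genes fell under 0.05. On the list of drug efflux and phenicol resistance, 2 genes were tested, and catB rose. catA, a symbol with the same ambiguity, lay at -0.78 (adjusted p = 0.0697). Adjustment over the list alone left its unadjusted p of 0.0241 (edgeR test) unchanged. The 2 rows differ in size, with 636 bases for catB and 939 for catA. Whether either gene encodes phenicol resistance was not tested. Calls ended for phaC and fdhE without control replicates 1 or 2 or florfenicol replicates 2 or 3 (adjusted p up to 0.0745 and 0.125), for fghA without control replicate 2 or florfenicol replicates 2 or 3 (up to 0.0793), for exbB without florfenicol replicate 2 (0.08) or with quantile normalization in limma (0.0523) and for fhuB without control replicate 2 (0.0537). The call of fdhE also ended in 4 limma fits (up to 0.0613) and with library totals alone in edgeR (0.0537). Over the 17 lists tested, camera called 0 at an adjusted p under 0.05, also 0 with an estimated correlation, and fry, which asks only whether a list's genes move 1 way on balance, called 3. The 4 lists at 0.0569 passed in the limma fit on FPKM with a pseudocount of 1 (adjusted p = 0.0342 for ribosome assembly and 0.0451 for the other 3) and without florfenicol replicate 1 (0.0222 and 0.034). Ribosomal proteins, ribosome assembly and oxidative stress defence passed without control replicate 3 (0.0451 each). With all libraries and an estimated correlation, the adjusted p was 0.738 for secretion and 0.701 for the other 4 of these lists.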

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

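DESeq2, edgeR with median-ratio factors or library totals only, the length-trend correction, the fit without rows of 200 bases or less and the share without nosZ were chosen after seeing the data. No gene called in the edgeR test was called in the opposite direction under any of the alternatives run. With 1 library left out, counts ran from 133 higher and 230 lower (control replicate 2) to 846 and 854 (control replicate 3). Fewer samples alone lower such counts. Control replicate 3 was the control nearest the florfenicol libraries on the first principal component, at -8.346 against -35.76 and -23.8. Whether this is why leaving it out raised the counts was not tested. limma on libraries rescaled to an equal sum called 471 higher, a shift its scaling builds in (median -0.11). A fold of at least 2 left 177 higher and 308 lower by construction. The replicate numbers were not taken to pair the samples, since deviations of equal-numbered libraries correlated at 0.37, -0.003 and 0.4, not above 0.1 for every pair. Number 2 lay between 1 and 3 on both principal components in each group, so its low correlation does not exclude a pairing, which stays open. The second component also ran in replicate order, at 7.017, -1.6 and -19.18 in the controls and 18.23, 4.194 and -8.654 with florfenicol. As hints of a link for numbers 1 and 3, the differences between these replicates correlated across genes at 0.432 between the groups, and 4 of 6 libraries correlated best with their own number. With the replicate block 1041 were higher and 1027 lower, and ribosomal proteins, ribosome assembly and secretion passed (adjusted p = 0.0237 each); aceB had a log2 fold change of -4.73. Without the block, the adjusted p of these 3 lists with an estimated correlation was 0.701, 0.701 and 0.738. All other counts stayed within 1.5 times; DESeq2 called 818 and 818, with 91 adjusted p-values missing.

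No list passed camera in the edgeR fit, and 4 of them, at 0.0569, passed in other fits; the cause was not tested. For ribosomal proteins, ribosome assembly, bc1 and oxidases, and secretion in this order, adjusted p was 0.0451, 0.0342, 0.0451 and 0.0451 with limma (pseudocount 1, with or without trend), 0.037, 0.0221, 0.036 and 0.0356 (pseudocount 5) and 0.0479, 0.0411, 0.0479 and 0.0479 (median-ratio scaling). With a pseudocount of 0.1 the last 3 gave 0.0366, 0.0459 and 0.0459, and equal-sum scaling gave ribosome assembly 0.0308. Leaving out 1 library gave 0.034 to 0.14, 0.0222 to 0.118, 0.034 to 0.118 and 0.034 to 0.14, and 0.0451 (without control replicate 3) to 0.218 for oxidative stress. fry gave 0.0338 for DNA damage, bc1 and oxidases, and molybdenum cofactor; no list passed with an estimated correlation. Directions that turned were of lists and genes far from the threshold: aminoacyl-tRNA synthetases (0.929 without control replicate 3; 0.488 to 0.929 with 1 library left out), flagellum (0.985 quantile, 0.781 without control replicate 3, 0.945 without florfenicol replicate 2; 0.627 to 0.971 with 1 left out) and one-carbon oxidation (0.979 without florfenicol replicate 3; 0.488 to 0.979 with 1 left out).

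Log2 fold changes turned for flgI (0.0442 without control replicate 3; -0.441 to 0.0442 with 1 left out), atpD (0.0278 without control replicate 1; -0.232 to 0.0278 with 1 left out) and recA: -0.0126 (limma, median-ratio), -0.119 (equal sum), -0.0223 (no filter), -0.00767 (filter at 10), -0.0111 (edgeR with median-ratio factors, and DESeq2), and -0.0195, -0.0382, -0.0374 and -0.026 without control replicates 1 and 3 and florfenicol replicates 1 and 3 (up to 0.0525 without control replicate 2). Of 64 named genes called, 36 lost the call without some library, most often control replicate 2 (35) or florfenicol replicate 2 (31), 13 under some other setting, and 28 under none. The denitrification share difference was -0.727 percentage points, -0.877 without the 10 genes of highest FPKM, as a smaller sum gives, and -0.151 without nosZ, its largest member. In simulation with 200 changed genes, changes of 1.5-fold were mostly missed (2.99% recovered). With 1383 genes called, the adjusted threshold of the real test was less strict, so that share does not describe it.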

Other observations

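The tests in this part were chosen after the results were seen, and so were the genes named. Among 47 sets of at least 4 named genes that share the first 3 letters of their symbol, some moved as sets. All 4 iol genes of inositol breakdown fell (median log2 fold change -1.19, camera adjusted p = 0.0025), as did all 4 cho genes of choline transport (-1.18, adjusted p = 0.014), and all 4 cyo genes rose (0.95, adjusted p = 0.0141). With an estimated correlation, the adjusted p was 0.738 for each of these 3 sets. Of 5 que genes of queuosine synthesis 4 rose, and of 6 pur genes of purine synthesis 4 rose and 1 fell, but neither set passed (adjusted p = 0.0734 and 0.256). Of 4 ugp genes of glycerol phosphate uptake 3 fell (adjusted p = 0.208).

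Calls for neighbouring genes came in stretches. In the order of locus numbers, 21 runs of at least 5 tested loci were lower throughout and 5 were higher throughout. Shuffling the loci 10000 times gave at most 4 of either, so a random scatter of changed loci is argued against (permutation p = 1e-04, the smallest possible). The runs included phoB, phoU, pstA and pstC (6 loci, median -1.83), iolE, iolD and iolC (6 loci, -1.36), cobA (EO213_06115), nirJ and katG (11 loci, -1.42), and cyoD to cyoA (7 loci, 0.82). Shared transcripts are a candidate explanation that the file, which holds no operon map, does not test, and reads spilling over between neighbours stay open too.

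Around the strongest rises, the 2 loci on either side of catB had log2 fold changes between 0.23 and 0.87, and those around EO213_21590 between -0.25 and 0.65; 1 locus at each passed the test.

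The groups differed by 1383 called genes, and the highest count of the other splits of the 6 libraries was 0. The real split was the 1 of 10 with as many, and 10 splits are too few for a share under 0.05.

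Libraries of each group were spread along the difference between groups. Replicates 3 and 1, chosen as the pair farthest apart on the first principal component in each group, differed in a profile that correlated with the florfenicol effect across 4684 genes at 0.48 in the controls and 0.354 in the florfenicol libraries; that choice favours positive values, so they only describe the spread. Gene length bias as the whole cause is argued against, since removal of the length trend left 0.461 (bootstrap SD 0.015) and 0.338 (0.019). Exposed material mixed into control replicate 3 is argued against for that library: its catB level was 1.32% of the florfenicol mean, where its position needs 31.6%. A difference in growth state between cultures may be behind the spread and was not tested.

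Of 51 tested rows of 70 to 95 bases, the size of transfer RNAs, 21 were higher and 2 lower, with a median log2 fold change of 1.0. They took 0.0707% ± 0.0344 of reads in the controls and 0.139% ± 0.0409 with florfenicol (SD, n = 3), with overlap, since control replicate 3 held 0.110% and florfenicol replicate 1 held 0.0941%. ssrA (354 bases) exceeded rnpB (368 bases) by 1.74 (SE 0.25) on the log2 scale. These are gene sizes, and the lengths of the RNAs in the cell were not measured. The difference therefore argues against better retention of short RNA for ssrA only if both RNAs are as long as their genes. For the rows of 70 to 95 bases, retention and a change in the cell cannot be told apart, since retention could end below 96 bases. Rows of 96 to 200 bases had a median of only 0.183. Among all 4684 tested genes 722 were higher and 661 lower, and of these 93 rows 14 were higher and 3 lower. ffs, the signal recognition particle RNA of 97 bases, was among the higher ones (2.80, SE 0.876, adjusted p = 0.0448) on 2, 0 and 1 reads in the controls and 7, 3 and 11 with florfenicol, and an effect of florfenicol on these RNAs stays untested.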
